A study of Mus musculus with 6 samples.

How the data were processed

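Kit+ cells were taken from the spleens of female wild-type C57BL/6 mice by bead selection with a CD117 antibody. The mice were untreated or had received phenylhydrazine (PHZ), a drug that lyses red cells and causes anaemia, at 100 mg/kg by subcutaneous injection 1, 3 or 7 days earlier. Per the labels' protocols, 15000 cells were loaded onto Seq-Well arrays holding 110000 capture beads. There are 6 libraries: 2 controls and 2 at day 3, from separate mice, and 1 each at day 1 and day 7. Replicate 1 has all 4 conditions and replicate 2 has a control and a day 3 library.

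Reads were aligned to mm10 and cells were handled with Seurat, per the submitters' processing notes, which give no versions and do not name the counting tool. The deposited matrices hold whole-number UMI counts per gene and cell, not normalised. They were used as deposited, library by library. The authors' metadata give each cell a class, a cell cycle phase and the percent of its counts from mitochondrial genes. The authors' cell cycle scores and phases were read from the same deposited metadata; the scores entered no test. Every deposited cell had at least 401 UMIs, at least 251 genes and under 20.0% mitochondrial counts. The matrices hold 0 genes named as mitochondrial and 0 whose names start with Rps or Rpl, so those genes are not measured here. The integrated matrices hold the same counts as the separate ones and were not used here. How the authors named the classes, and whether doublets were removed, is not stated; no doublet caller was run, and leaving out the top 5% of cells by UMIs was an alternative.

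The 25251 cells gave between 5009519 and 27021037 UMIs per library. Intervals on shares are exact Clopper-Pearson 95% intervals and intervals on counts are exact Poisson ones. Both cover counting error only. A fold against a group with 0 counts is given as a lower bound, against a floor of 3 counts over the group.

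For day 3 against control, UMI counts were summed per library over all cells, or over the cells of 1 class. Cells are not replicates, so each test compares 2 libraries with 2 libraries. The test was edgeR 4.0.16 quasi-likelihood with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05, which leaves 2 residual degrees of freedom. A class was fitted where all 4 libraries had at least 20 of its cells, which left 13 of the 18 classes. The day 3 effects in the largest pair of erythroid classes were compared by an interaction term with a term per library. Class shares were tested with the same tool on numbers of cells. There the spread was pooled over all classes, so those p-values rest on more than the 2 residual degrees of freedom. The 19 gene lists and 15 marker lists, 34 in all, were fixed before the data were examined. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry. DESeq2 1.42.0 was an alternative; R was 4.3.3. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 did the rest.

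The time course in replicate 1 has 1 library per day and no test. It gives log2 ratios of counts scaled to the library total (CPM) to control replicate 1, with a prior of 0.5 counts. List medians are set against 10000 random lists matched on mean expression. A gene was counted as beyond both yardsticks where its ratio exceeded the difference between the 2 controls and that between the 2 day 3 libraries. For the cell cycle, each cell was thinned to 1000 UMIs and counted as positive with at least 2 UMIs of the S phase or the G2 and M phase list. Cells with fewer UMIs were left out, between 560 and 2906 per library.

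Genes named for each tested comparison are the 10 largest rises and the 10 largest falls by log2 fold change. They had to pass an adjusted p of 0.05, hold at least 50 counts over the 4 libraries and place both day 3 libraries on the same side of both controls. Predicted genes, ribosomal protein genes and mitochondrial genes were not named. Where fewer than 5 passed, the genes of smallest p were added as values. From each list up to 4 members past the test with the largest change were named, or otherwise 2 of the highest mean expression. Kit, Gata1, Gata2, Epor, Tfrc, Klf1, Hba-a1 and Hbb-bs are always given. The text gives a part of these; a gene outside the rule is said to be.

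Some steps were chosen after the data had been seen. Cells with late erythroid RNA were defined as those with at least 3 UMIs of the 14 late erythroid progenitor markers after thinning to 500 UMIs. That depth and threshold were set after looking at the distributions, and between 117 and 733 cells per library with fewer UMIs were left out. Sums over 8 lineages, a split into cells with and without late erythroid RNA, and a total without the classes Erythroid4 and Erythroid5 were added at the same stage. The rule for naming clusters of an own clustering, an alternative with 19 clusters from 30 principal components at a resolution of 0.5, was tightened after the leading genes of 1 cluster had been seen. Medians of lists within own clusters, the overlap of control and day 3 cells of a class over own clusters (the sum over clusters of the smaller of both shares), list levels within single classes and the cell cycle shares within Monocytes_progenitors were also computed after the data were seen.

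The fits were tested on simulated data drawn from the real means, with 200 genes changed. The changed genes were drawn only from those of higher expression in controls. In all Kit+ cells, on 16417 genes, 67.0% of 4-fold changes and 4.0% of 2-fold changes were recovered. The same 2 shares were 92.0% and 46.0% in Erythroid1 on 10412 genes, and 95% and 21.0% in Erythroid5 on 9389 genes. In Erythroid4, on 8730 genes, they were 85.0% and 18.0%, and in HSPCs, on 9609 genes, 93.0% and 24.0%. In B_Lineage, on 9181 genes, they were 81.0% and 10.0%, and in T_Lineage, on 6764 genes, 85.0% and 4.0%. In cells with late erythroid RNA, on 12163 genes, they were 91.0% and 39.0%. False calls made up at most 6.5% of calls. Simulated genes varied independently at the fitted dispersion, and as many were raised as lowered. These shares therefore do not cover library differences shared over genes, changes as widespread as those found here, or genes low or absent in controls. An exact permutation test of 2 against 2 libraries cannot give a 2-sided p under 0.333, so none is given.

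Other alternatives were RLE size factors, no filter on low counts, globin genes left out, a replicate block, cells of at least 1000 UMIs, the same cells thinned to 1000 UMIs and each library left out in turn. With 1 library left, that library is assumed to vary like the other group.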

Results

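The series asks how Kit+ progenitors of the mouse spleen respond to acute haemolytic anaemia. Single-cell RNA profiles were collected from 25251 cells in 6 libraries. Control replicate 1 had 4809 cells and 18640391 UMIs, and control replicate 2 had 2309 cells and 5009519. PHZ day 3 replicate 1 had 3454 cells and 27021037 UMIs, and replicate 2 had 6851 cells and 26321598. The single day 1 library had 3850 cells and 22026358 UMIs, and the single day 7 library had 3978 cells and 22934042. Median UMIs per cell ran from 1160 in control replicate 2 to 3873.5 at day 1. Control replicate 2 stood apart: it was the shallowest library, had a median of 4.58% mitochondrial counts against 7.54% to 10.8% in the others, and had counts in 30639 genes against at most 26703.

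The first question was how the whole Kit+ population changed by day 3. Cells with late erythroid RNA, which hold several UMIs of genes such as Klf1, Epor and the Rh antigen gene Rhd, were rare in controls and the majority on day 3. They made up 4.36% (95% interval 3.78% to 5.0%) of cells in control replicate 1 and 5.84% (4.85% to 6.97%) in control replicate 2. On day 3 they were 56.8% (55.1% to 58.6%) in replicate 1 and 74.9% (73.8% to 76.0%) in replicate 2. All of these are shares of the cells that the bead selection returned, so its purity can set them. The class B_Lineage alone made up 37.1% and 19.2% of cells in controls and 16.4% and 6.60% on day 3. In the class T_Lineage, which should lack these RNAs, the share was 0% in both controls, with upper limits of 1.53% and 1.63%. It was 3.33% and 2.08% on day 3. Median depths there were 4814 and 2047 UMIs in controls and 4132 and 2302.5 on day 3; over all cells they were 2292 and 1487 in controls and 2627 and 1387.5 on day 3. Between 6.01% and 24.7% of cells in these 4 libraries lay within 1 UMI of the threshold. T_Lineage does not stand for every other class, as several had larger shares on day 3, given below with their classes. Of the day 3 cells with late erythroid RNA, 72.0% in replicate 1 and 73.5% in replicate 2 lay in erythroid classes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the share of cells with late erythroid RNA rose by 3.70 on the log2 scale (SE 0.32, adjusted p = 6.2e-04). It was higher in both day 3 libraries. That fit held only the cells with and without this RNA, whose numbers are complements. Sharing the spread between them, at a threshold set after seeing the data, can make the p too small.

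**Figure D1:**
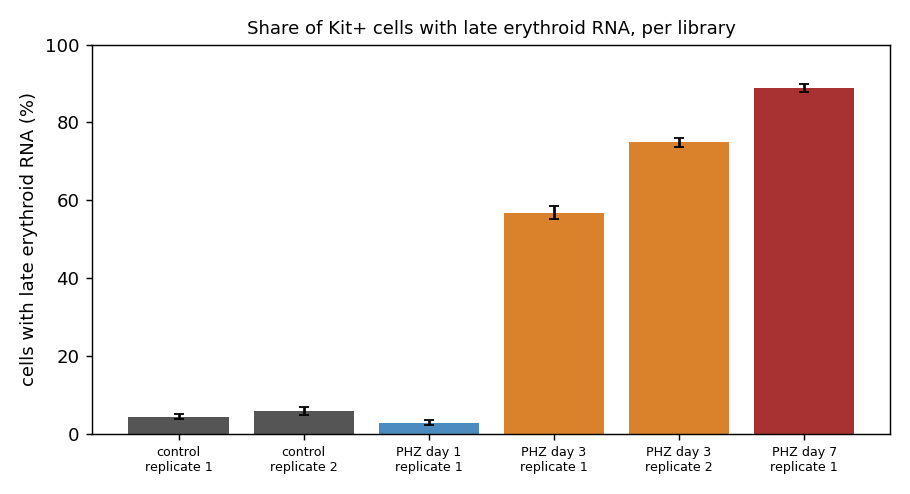
Share of Kit+ cells with late erythroid RNA (percent, vertical axis) in each of the 6 libraries, with exact binomial 95% intervals as bars. Both controls and day 1 lie under 7.0%, the day 3 libraries at 56.8% and 74.9% and day 7 at 88.8%.

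Erythroid genes rose together in the summed RNA of all Kit+ cells. The erythroid regulator Klf1 went from 25.6 and 58.3 CPM in controls to 494 and 597 CPM on day 3, a log2 fold change of 4.09 (SE 0.40). Gata1, the central transcription factor of erythropoiesis, rose by 3.90 (SE 0.54), the erythropoietin receptor gene Epor by 3.74 (SE 0.32) and the transferrin receptor gene Tfrc by 3.81 (SE 0.33). The erythropoietin-induced hormone gene Erfe rose by 6.05 (SE 0.56) and the sialomucin gene Podxl by 7.78 (SE 0.76). Their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.0044 to 0.0072. Kit itself had a log2 fold change of -0.54 (adjusted p = 0.29), Gata2 one of 1.01 (adjusted p = 0.14), Hba-a1 one of 1.02 (adjusted p = 0.42) and Hbb-bs one of 1.17 (adjusted p = 0.32) in the same edgeR fit with Benjamini-Hochberg adjustment, so none of these passed.

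In mm10 coordinates from the GENCODE annotation, Kit lies on chromosome 5 at 75574916 to 75656722 and Gata2 on chromosome 6 at 88193891 to 88207032. Gata1 lies on chromosome X at 7959260 to 7978071 and Klf1 on chromosome 8 at 84901928 to 84905291. Epor lies on chromosome 9 at 21958897 to 21963506 and Tfrc on chromosome 16 at 32608920 to 32632794. Hba-a1 lies on chromosome 11 at 32283511 to 32284465 and Hbb-bs on chromosome 7 at 103826534 to 103828096. All 8 are protein-coding. The alpha and beta globin genes each have near-identical copies between which the counting may have split reads, so single globin values are uncertain.

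The largest rises included genes with no UMI in either control. Cda, a cytidine deaminase gene, had 0 counts in controls and 2718 on day 3, so it was at least 402-fold higher. C2cd4a was at least 296-fold higher and the meiotic gene Rnf212 at least 26.3-fold higher. The pseudogene Apol10c-ps, the T cell receptor segment Trgj1 and the histone gene H2ac12 also had 0 control counts, with bounds of at least 12.1-fold, 11.8-fold and 9.90-fold higher. Sfrp4, an inhibitor of Wnt signalling, rose from 2 to 1282 counts and Fam124a from 6 to 2056. Among the largest falls, the complement gene C6 went from 724 counts to 0, at least 544-fold lower, and Timd4, a receptor of resident macrophages, from 355 counts to 1. Vstm4, Hs3st2, Cd163l1 and Akr1b7 went to 0, at least 145-fold, 119-fold, 44.4-fold and 53.4-fold lower. The immunoglobulin segments Ighv5-15, Igkv1-99, Ighv9-2 and Ighv1-66 also went to 0. Such segments can mark single B cell clones, and Ighv5-15 differed between the 2 controls, at 52.6 and 1.20 CPM.

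In all, 6142 of 16964 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3653 higher and 2489 lower. The count was 3858 without control replicate 1 and 3875 without control replicate 2. The share of higher genes among the calls was 59.5%, and ran from 50.1% without day 3 replicate 1 to 74.4% without control replicate 1.

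Among the gene lists, red cell genes moved furthest. All 19 red cell membrane genes rose, with a median log2 fold change of 4.04, among them Rhag (4.91), the adducin gene Add2 (4.83), Cldn13 (4.67) and Dmtn (4.62). All 14 late erythroid progenitor genes rose (median 3.77), including Rhd (4.31) and Icam4 (4.29). Of 15 heme synthesis genes 14 rose (median 2.66), including Cpox (3.83), Abcb6 (3.64) and Alad (3.25). Of 17 iron handling genes 10 rose (median 0.96), including Steap3 (4.19) and Tfr2 (3.67). Of 18 erythroid transcription factor genes 11 rose (median 1.19), including Tal1 (3.89) and Gfi1b (3.53). Of 13 erythroblast genes 5 rose (median 1.77), including Slc4a1 (3.90), and of 11 early erythroid progenitor genes 6 rose and 1 fell (median 1.71), Ryk rising by 3.58. Camera adjusted p-values with Benjamini-Hochberg adjustment on the edgeR counts ran from 1.4e-10 for red cell membrane to 0.012 for early erythroid progenitor genes. With an estimated correlation the adjusted p-values of these 7 lists ran from 0.53 to 0.67, so none kept its call. By fry, red cell membrane (adjusted p = 0.012), heme synthesis (0.010), late erythroid (0.030), iron handling (0.012) and transcription factor genes (0.0098) passed, and erythroblast (0.12) and early erythroid genes (0.061) did not. Adjusted over the list alone, 13 iron handling genes and 12 transcription factor genes rose.

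Genes of dividing and growing cells rose as well. All 37 S phase genes rose (median 2.61), with Rrm2, Cdc6 (3.38), Tyms (3.27) and Chaf1b (3.10) the furthest. Of 51 G2 and M phase genes 50 rose (median 2.56), led by Nek2 (3.39), Hmmr (3.34), Cdc20 (3.32) and Birc5 (3.26). All 22 ribosome biogenesis genes rose (median 1.85), including Nhp2 (2.78) and Ncl (2.17), and 26 of 27 oxidative phosphorylation genes (median 1.45), including Cyc1 (2.13). Of 17 oxidative stress genes 14 rose (median 1.61), including Gclm (3.10) and Prdx2 (3.07). Of 16 ATF4 stress genes 7 rose and 1 fell (median 0.80); the asparagine synthetase gene Asns rose by 4.56 and Ddit4 fell by 2.66. Camera adjusted p-values on the edgeR counts ran from 1.6e-17 for G2 and M phase to 0.037 for ATF4 stress genes with Benjamini-Hochberg adjustment. With an estimated correlation they ran from 0.53 to 0.56, so no call held, and by fry from 0.010 to 0.029.

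Several lists of T, NK and dendritic cell genes were lower. All 15 T cell genes fell (median -3.00), including Cd4 (-3.48), Cd3e (-3.42), Trac (-3.18) and Cd3d (-3.18). Of 13 NK cell and innate lymphoid genes 9 fell (median -3.05), including Ccl5 (-4.17) and Klrd1 (-3.39), and of 13 dendritic cell genes 10 fell (median -2.51), including Cd209a (-3.46), Flt3 (-3.20), Itgax (-2.88) and H2-Eb1 (-2.87). Of 14 B cell genes 2 fell (median -2.55), including Cd22 (-2.70), and adjusted over the list alone 11 fell. Of 14 monocyte and macrophage genes 1 fell, Mrc1 (-4.61), with a list median of -2.07. Interferon response genes had a median of -0.99 with 3 of 22 lower, BMP and SMAD signalling genes -1.50 with 5 of 11 lower, including Id3 (-2.64) and Id2 (-2.37), and genes induced by handling cells -1.73 with 6 of 17 lower and 1 higher. Nr4a1 (-2.91) and Junb (-2.11) were among the last. Camera adjusted p-values on the edgeR counts with Benjamini-Hochberg adjustment ran from 6.2e-07 for T cell genes to 0.037 for handling genes. With an estimated correlation they ran from 0.53 to 0.67, so no call held. By fry only the dendritic cell list passed among these 8 (adjusted p = 0.034), and the T cell list had 0.061.

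The other 13 lists did not pass in camera at a preset correlation. The globin list had a median of 1.02 (adjusted p = 0.22), the Kit and GATA2 circuit -0.06 (0.49) and Epo and STAT5 targets 0.84 (0.071), by camera on the edgeR counts with Benjamini-Hochberg adjustment. Within the circuit list, Tal1, Ssx2ip (3.77), Samd14 (3.09) and Zfpm1 (2.55) rose, while its median and camera direction differed in sign. By fry the circuit list (adjusted p = 0.048) and glycolysis genes (0.011) passed and the other 11 lists did not. Glycolysis and hypoxia genes had a median of 0.54 (adjusted p = 0.071) with Slc16a1 rising by 3.51 and Slc2a1 lower, at 788 counts in controls and 331 on day 3, and cholesterol synthesis genes 0.32 (0.21). The p53 targets had -0.25 (0.50), stem and multipotent progenitor genes -0.39 (0.61) with Procr (-3.43) and Flt3 lower, and endothelial and stromal genes -1.40 (0.066). Megakaryocyte genes had 1.83 (0.13), mast cell and basophil genes -0.74 (0.67), neutrophil and granulocyte progenitor genes 1.51 (0.13), eosinophil genes -0.45 (0.15) with Ccr3 at -5.33, and plasma cell genes -2.12 (0.13).

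The next question was whether these changes appear within cell classes. In Erythroid1, whose leading genes include Podxl and Mt2, Tfrc rose by 1.81 (SE 0.23) and Klf1 by 0.82 (SE 0.22), while Kit fell by 1.49 (SE 0.21), with adjusted p-values of 9.5e-04, 0.034 and 0.0017 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cda, the apolipoprotein gene Apol8 and C2cd4a had 0 control counts there and were at least 17.1-fold, 15.9-fold and 14.3-fold higher. The anion exchanger gene Slc4a1 and the transcription factor gene Sox6 were at least 7.81-fold and 8.55-fold higher. Cd7 (-8.01), Ifi27l2a (-7.24), Dtx1 (-6.74), Cd180 (-6.67) and Ltb (-6.44), genes of lymphocytes and myeloid cells, fell. In all, 1495 of 10765 genes changed, 461 higher and 1034 lower. Without day 3 replicate 1 the count was 485, without day 3 replicate 2 it was 494 and without control replicate 2 it was 2681. Controls held 101 and 41 cells of this class, with medians of 1745 and 1079 UMIs, against 33490.5 and 18527 on day 3. In an own clustering, made without aligning the libraries, 792 of 853 day 3 cells of this class lay in 1 cluster, whereas 69 of 142 control cells lay in another, and the shares of cells per cluster overlapped by 11.03%. Such a clustering can also part cells of 1 kind whose RNA changed.

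Erythroid5 and Erythroid4, the erythroid classes with the most cells, changed in more genes. In Erythroid5 the rises included Tlcd4, at least 67.0-fold higher, Cda, at least 21.3-fold higher, and Plek2, at least 17.8-fold higher. The falls included Mrc1 from 76 counts to 1, Zap70 from 59 to 2, Eomes from 60 to 2, Cd6 from 50 to 2 and Cd8b1 (-6.70), genes of macrophages and T cells. Klf1 rose by 2.94 (SE 0.50) in Erythroid5 and by 4.13 (SE 0.40) in Erythroid4, and Epor by 2.92 and 2.94, while Kit fell in Erythroid4, at -1.95 (SE 0.34). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4380 of 9785 genes changed in Erythroid5, 2119 higher and 2261 lower, and 3997 of 9278 in Erythroid4, 1869 higher and 2128 lower. Within these classes, however, the shares of cells with late erythroid RNA differed: 6.84% and 14.5% of control cells in Erythroid5 against 82.0% and 83.4% on day 3, and 10.02% and 8.93% of control cells in Erythroid4 against 84.0% and 91.4%. In Erythroid1 the control shares were 58.4% and 73.7% against 82.2% and 85.8%. Control and day 3 cells also lay in different own clusters, the shares overlapping by 3.04% in Erythroid5 and 3.71% in Erythroid4. Without day 3 replicate 1 the Erythroid5 count was 2751, and without day 3 replicate 2 it was 2664 in Erythroid5 and 2349 in Erythroid4.

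**Figure D2:**
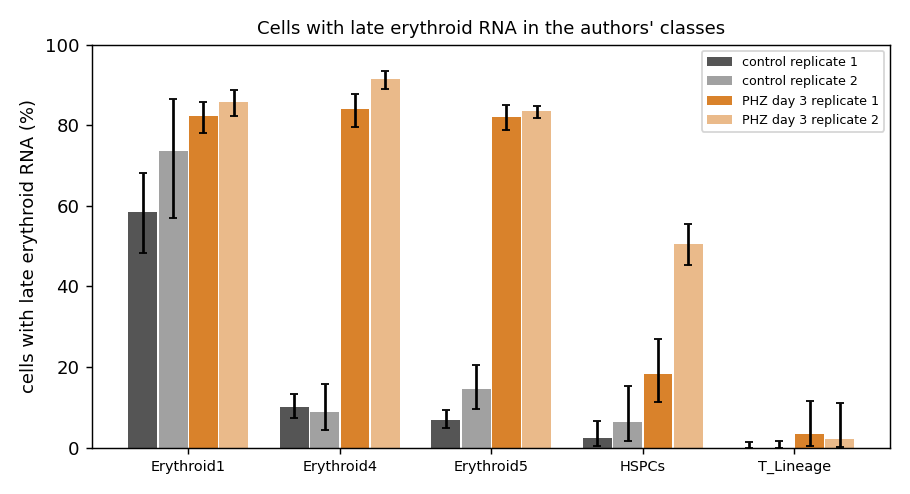
Share of cells with late erythroid RNA (percent, vertical axis) in 5 of the authors' classes, for 2 control and 2 day 3 libraries, with exact binomial 95% intervals. The control shares lie between 6.84% and 14.5% in Erythroid4 and Erythroid5, and at 58.4% and 73.7% in Erythroid1.

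Restricting the comparison to cells with late erythroid RNA, or late erythroid cells, whatever their class, gave smaller log2 fold changes for erythroid and cell cycle genes than in all Kit+ cells. Klf1, Tfrc, Epor, 5 red cell membrane genes and 1 heme synthesis gene are among the markers that select these cells, so the selection in part sets their values. Over the other 14 members of either list the medians were 1.05 for red cell membrane and 0.72 for heme synthesis genes in these cells, against 4.0 and 2.75 in all Kit+ cells. The median log2 fold change was 0.99 for red cell membrane genes, 10 of 19 higher, and 0.78 for heme synthesis genes, 6 of 15 higher. It was 0.84 for G2 and M phase genes, 26 of 51 higher, and 0.63 for S phase genes, 13 of 37 higher. Tfrc rose by 1.48 (SE 0.26) and Klf1 by 0.74 (SE 0.18), Kit fell by 1.32 (SE 0.23), and Podxl rose by 5.77 (SE 0.54). The largest falls included Itgad, from 77 counts to 2, Mrc1 (-6.81), Cd5l (-6.31), Marco (-6.13) and C1qa (-6.02). B cell genes (median -3.47, 13 of 14 lower) and T cell genes (median -3.14, 13 of 15 lower) were also lower in these cells. Camera adjusted p-values on the edgeR counts with Benjamini-Hochberg adjustment were 5.2e-05 for red cell membrane, 4.7e-04 for heme synthesis, 3.1e-11 for G2 and M phase and 4.8e-07 for S phase, and 5.2e-05 and 4.8e-07 for B and T cell genes. With an estimated correlation all 6 adjusted p-values were 0.48 or 0.49, and by fry only heme synthesis passed (adjusted p = 0.049). In all, 2097 of 12575 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 887 higher and 1210 lower. The count was 1019 without control replicate 1, 846 without day 3 replicate 1 and 1034 without day 3 replicate 2. Controls held 193 and 115 such cells, against 1797 and 4584 on day 3.

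In HSPCs, as the authors named this class, the leading genes include Angpt1, Cd34, the mast cell gene Cpa3 and the granulocyte genes Mpo and Ctsg. Of 16 red cell membrane genes 11 rose there (median 3.26), of 14 heme synthesis genes 7 (median 0.95) and of 14 late erythroid progenitor genes 8 (median 1.48). Camera adjusted p-values on the edgeR counts with Benjamini-Hochberg adjustment were 8.7e-08, 7.0e-04 and 3.3e-06, against 0.39, 0.43 and 0.39 with an estimated correlation and 0.067, 0.12 and 0.10 by fry, so no call held. Spectrin gene Sptb was at least 10.8-fold higher and Tfrc rose by 2.05 (SE 0.25), Add2 from 2 to 371 counts and Podxl from 1 to 243. Kit fell by 0.90 (SE 0.28), with an adjusted p of 0.044 in edgeR with Benjamini-Hochberg adjustment. The mast cell protease gene Cma1 (-5.44) and the T cell genes Icos (-5.05), Cd8a (-4.92) and Bcl11b (-4.54) fell. Of 9919 genes 1844 changed, 881 higher and 963 lower; DESeq2 called 895, and without day 3 replicate 1 and replicate 2 the counts were 1010 and 319. The shares of control and day 3 HSPCs per own cluster overlapped by 41.1%, and the same cluster held the most cells of both. In the cluster that holds 60 of 205 control and 325 of 525 day 3 HSPCs, edgeR called 8 of 9275 genes, 1 higher and 7 lower, with 1363 at an unadjusted p under 0.05, and the red cell membrane list had a median of 0.78. The share of cells with late erythroid RNA in this class was 2.34% and 6.25% in controls and 18.3% and 50.5% on day 3.

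Cell cycle genes also rose in the class Monocytes_progenitors, and a few G2 and M phase genes rose in T_Lineage. The name Monocytes_progenitors is the authors': its 10 leading genes, among them Ccnd1, S100a4 and Itgax, held 1 marker of dendritic cells and none of monocytes. In this class the largest rises were the mitotic genes Aspm, from 1 to 117 counts, Ccna2, from 2 to 136, Sgo2a, from 1 to 69, Plk1, from 2 to 65, and Ccnb2 (5.78). Of 48 G2 and M phase genes 37 rose there (median 3.51) and of 37 S phase genes 20 (median 1.78); the T cell genes Trbc2, from 89 counts to 1, and Cd8a (-3.57) fell. These values depend on which cells are grouped: the cluster of an own clustering that holds 553 of the 619 cells of the class had medians of 0.93 for G2 and M phase genes, none of which passed, and 1.14 for S phase genes, 4 of 37 higher. In all, 15 of 9009 genes passed in that cluster by edgeR, 8 higher and 7 lower, with 1251 at an unadjusted p under 0.05; DESeq2 was not run on own clusters. In T_Lineage the proliferation marker gene Mki67 rose by 4.26 (SE 0.48), Top2a by 3.88 (SE 0.40) and Kif15 by 4.01 (SE 0.62), and H2-Eb1 fell, at -2.97 (SE 0.46). Klf1 also rose in Monocytes_progenitors, from 2 to 50 counts. Late erythroid progenitor genes had medians of 3.39 there and 2.45 in T_Lineage. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 213 of 8818 genes changed in Monocytes_progenitors and 13 of 7207 in T_Lineage. Without control replicate 1 these counts were 17 and 50, without control replicate 2 they were 55 and 35, without day 3 replicate 1 they were 678 and 30, and without day 3 replicate 2 they were 1065 and 65. For S and G2 and M phase genes in Monocytes_progenitors, camera gave adjusted p-values of 7.0e-26 and 3.1e-45 on the edgeR counts with Benjamini-Hochberg adjustment, against 0.33 for both with an estimated correlation and 0.016 for both by fry. In T_Lineage 4 of 35 G2 and M phase genes rose (median 2.33), 25 adjusted over the list alone, with 5.5e-30 by camera, 0.24 with an estimated correlation and 0.076 by fry. The S phase median there was 1.03; none of the 28 genes passed over all genes tested and 9 were higher adjusted over the list alone, with 1.2e-14 by camera, 0.45 with an estimated correlation and 0.24 by fry. In the T cell-like own cluster with 385 T_Lineage cells this median was 0.50 and that of G2 and M phase genes 1.29. None of 7075 genes passed in that cluster by edgeR, and 390 had an unadjusted p under 0.05.

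In B_Lineage, 0 of 9590 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 725 had an unadjusted p under 0.05, and DESeq2 called 207. The count was 412 with a replicate block and 506 with no filter on low counts, and 19 of 8634, all higher, in the own cluster that holds 1928 of these cells. Cells with late erythroid RNA were 0.114% and 1.24% of the class in controls and 3.21% and 44.8% on day 3. Among the genes of smallest p were Podxl, with 1 control count and 138 on day 3, Mt2 (5.83) and Cdc6 (5.30), and on the lower side Csf1r (-2.58). Leaving out 1 library gave 78 calls without control replicate 1, 157 without control replicate 2, 2274 without day 3 replicate 1 and 25 without day 3 replicate 2. Calls in the remaining classes were 1726 in Dendritic_cells, 537 in Macrophages_progenitors, 1806 in Neutrophils_progenitors1, 2286 in Plasma_cells, 1767 in Non-classical1 and 622 in Non-classical2. Cells with late erythroid RNA were at most 10.1% of any of these 6 classes in either control. On day 3 they were 22.0% and 53.6% of Dendritic_cells, 44.7% and 73.5% of Macrophages_progenitors, and 70.1% to 81.5% of the other 4 classes in either library. The shares of control and day 3 cells per own cluster overlapped by 81.8% in Macrophages_progenitors, 59.5% in Dendritic_cells, 35.7% in Neutrophils_progenitors1, 13.4% in Plasma_cells, 11.7% in Non-classical2 and 6.73% in Non-classical1. DESeq2 called 773, 258, 921, 1363, 1010 and 329 in these 6 classes, in the same order. With cells thinned to 1000 UMIs the counts were 229 in Dendritic_cells, 427 in Neutrophils_progenitors1 and 892 in Plasma_cells, and with no filter on low counts Non-classical2 had 4. Without the top 5% of cells there were 1107 in Dendritic_cells and 341 in Macrophages_progenitors, and with cells of at least 1000 UMIs 1184 in Neutrophils_progenitors1. Klf1 rose in each of these 6 classes. Among the falls were Ccr7 in Dendritic_cells, from 131 counts to 2, C6 and Timd4 in Macrophages_progenitors, both with 0 counts on day 3, and the eosinophil granule gene Prg2 in Neutrophils_progenitors1, from 1740 counts to 0. The name of that class is the authors': its leading genes include Prg2, Epx, Prg3 and Ear6, of eosinophils, beside neutrophil genes. In all Kit+ cells of day 3 replicate 1, the log2 ratio of Prg2 was 0.17 to the mean of both controls and negative to control replicate 1. The fall within the class therefore does not show a loss of Prg2 from the whole population. By the same edgeR test the count was 0 without day 3 replicate 2 in Dendritic_cells, Plasma_cells and Non-classical2, where 1527, 2074 and 582 genes had an unadjusted p under 0.05. It was 0 in Dendritic_cells without day 3 replicate 1 too, with 2146 such genes; DESeq2 was not run with a library left out. Other counts that moved by over 1.5 times were 1119 in Dendritic_cells, 144 in Macrophages_progenitors, 1056 in Non-classical2 and 1224 in Plasma_cells without control replicate 1. Without control replicate 2 they were 305 in Macrophages_progenitors and 1110 in Non-classical2. Without day 3 replicate 1 they were 1446 in Macrophages_progenitors, 990 in Neutrophils_progenitors1, 3 in Non-classical2 and 980 in Plasma_cells, and without day 3 replicate 2 they were 268 in Macrophages_progenitors, 772 in Neutrophils_progenitors1 and 1001 in Non-classical1.

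A further comparison asked whether the day 3 effect differed between Erythroid5 and Erythroid4. Control and day 3 cells of both classes were largely unlike, with own cluster shares overlapping by 3.04% and 3.71%. At most 14.5% of their control cells held late erythroid RNA. A difference here therefore does not show that erythroid stages responded differently. The S phase genes Pclaf, Esco2, Brip1 and Atad2 and the linker histone gene H1f5 had the higher effect in Erythroid5, by 1.89, 1.96, 2.66, 1.39 and 1.47 on the log2 scale. Btg2, an inhibitor of division, Ablim1, Xpo7, the fatty acid transporter gene Cd36 and Fam117a had the lower effect there, at -2.52, -2.01, -2.76, -2.80 and -2.46. By an interaction term in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13 of 10108 genes passed, 6 higher and 7 lower. The count was 507 without control replicate 1, 484 without control replicate 2, 5 without day 3 replicate 2, and 0 without day 3 replicate 1, where 315 genes had an unadjusted p under 0.05; DESeq2 was not run on this term.

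The shares of cells by class were compared next. T_Lineage went from 4.97% and 9.87% of cells in controls to 1.74% and 0.70% on day 3, and NK_cells from 0.64% and 3.94% to 0.46% and 0.16%. Erythroid1 went from 2.10% and 1.78% to 11.5% and 6.67%, and Erythroid5 from 13.6% and 11.2% to 22.3% and 40.6%. All erythroid classes together went from 27.5% and 20.7% to 49.6% and 63.9%. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 18 classes passed, the smallest adjusted p being 0.13; 5 had an unadjusted p under 0.05, and DESeq2 was not run on shares. Summed into 8 lineages, T lineage and NK cells fell by 2.67 on the log2 scale (adjusted p = 0.010), the class Epithelial_cells by 2.75 (0.014) and dendritic cells, monocytes and macrophages by 1.65 (0.042) in edgeR with Benjamini-Hochberg adjustment, each lower in both day 3 libraries. The name Epithelial_cells is the authors': all 57 cells lay in a dendritic cell-like own cluster, their leading genes include Fscn1, Il4i1 and Cxcl16, and 4 and 7 of them came from the day 3 libraries. The erythroid lineage did not pass (log2 fold change 1.23, adjusted p = 0.083). Among own clusters 3 rose, by 6.53, 5.23 and 5.44 (adjusted p = 0.010, 0.014 and 0.014 in the same edgeR test), each higher in both day 3 libraries, and none fell. Those 3 clusters were left unnamed by the marker rule and had medians of 1301, 593 and 5910 UMIs. The clustering did not align the libraries, so a change in RNA can itself form a cluster of day 3 cells. Their rise therefore does not show that 3 cell types expanded. The share tests pooled the spread over classes, lineages or own clusters, whose shares sum to a whole and are not independent. Their p-values can therefore be too small, and T lineage and NK cells alone took 5.61% and 13.8% in controls. The selection for Kit and the number of cells loaded can set shares, so all of these are shares of the selected cells.

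In replicate 1, the course over 7 days could be followed, with no test because each day has 1 library. On day 1, cells with late erythroid RNA were 2.87% (95% interval 2.36% to 3.45%), and late erythroid progenitor genes had a median log2 ratio of -0.19 to control replicate 1, within the ratio of 1.14 between the controls. Gpnmb, a gene of lipid-loaded macrophages, had a ratio of 8.84 and the coagulation factor gene F10 one of 5.97, and Trem2, another macrophage gene, had 257 counts against 3. The coagulation factor gene F7 had 0 counts in control replicate 1 and 212 on day 1. The granulocyte genes Mpo (-6.61) and Ctsg, with 1 count against 178, were lower, and Epx and Ear6, of eosinophils, had 0 counts on day 1 against 454 and 231. Mpo and Ctsg do not stand for all granulocyte RNA, as the authors' neutrophil classes went the other way. Those classes held 0.853% of cells and 0.786% of UMIs in control replicate 1, and 5.56% and 4.61% on day 1. Interferon response genes had a median of 0.62 and T cell genes 0.35, both at percentile 100.0 of the random lists, while the T cell ratio between the controls was 0.32. By day 3 the late erythroid median was 3.99 and by day 7 it was 4.92, when 88.8% (87.8% to 89.8%) of cells held late erythroid RNA. Ratios beyond both yardsticks were found for 1390 genes on day 1, 7699 on day 3 and 7883 on day 7. Genes with at least 100 counts numbered 10963, 11179 and 11113. Some genes exceed both yardsticks through library differences alone. That share was not estimated, so the day 1 number does not show a response.

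The globin list had medians of -1.18 on day 1, 0.23 on day 3 and 3.53 on day 7, and globins took 7.81% of UMIs on day 7 against 0.33% to 1.02% in the other replicate 1 libraries. The control 2 to control 1 yardstick of this list was -2.55, so only the day 7 value exceeded it. Against the mean of both controls the medians were -0.36, 1.03 and 4.28. In replicate 2, Hbb-bs went from 755 CPM in the control to 3237 CPM on day 3 and Hba-a1 from 131 to 661 CPM. Gata1 had log2 ratios of 0.46, 4.30 and 4.72 on days 1, 3 and 7, the first turning to -0.59 against the mean of both controls, and Klf1 -0.18, 4.27 and 4.79. Gata2 had -0.40, 1.52 and -0.45, and Kit -0.48, -0.49 and -0.16; with TMM scaling the day 7 value of Kit was 0.18. Genes highest on day 7 included Slc2a4, a glucose transporter gene with 705 counts against 1, the long noncoding RNA gene Redrum (8.16) and Fn3k (7.27). Stem and multipotent progenitor genes had a median of -1.51 and plasma cell genes -3.73 on day 7.

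**Figure D3:**
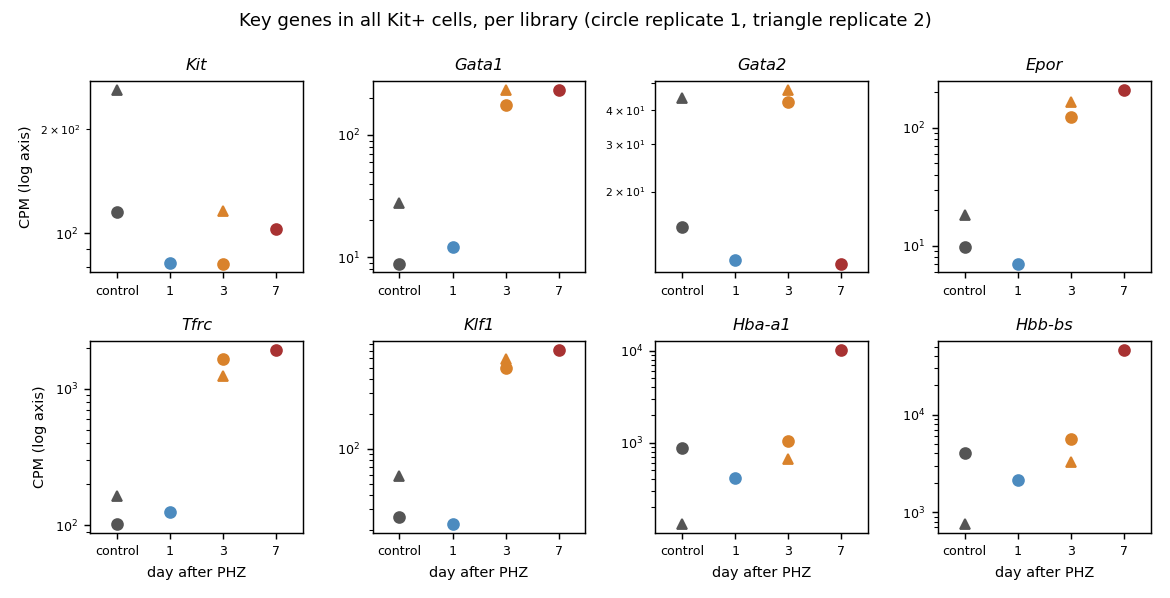
CPM of 8 key genes (vertical axis, log scale) in all Kit+ cells by day after PHZ, 1 point per library, circles for replicate 1 and triangles for replicate 2. Gata1 and Klf1 are higher in all day 3 and day 7 libraries than in controls, and Hba-a1 and Hbb-bs are highest on day 7.

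**Figure D4:**
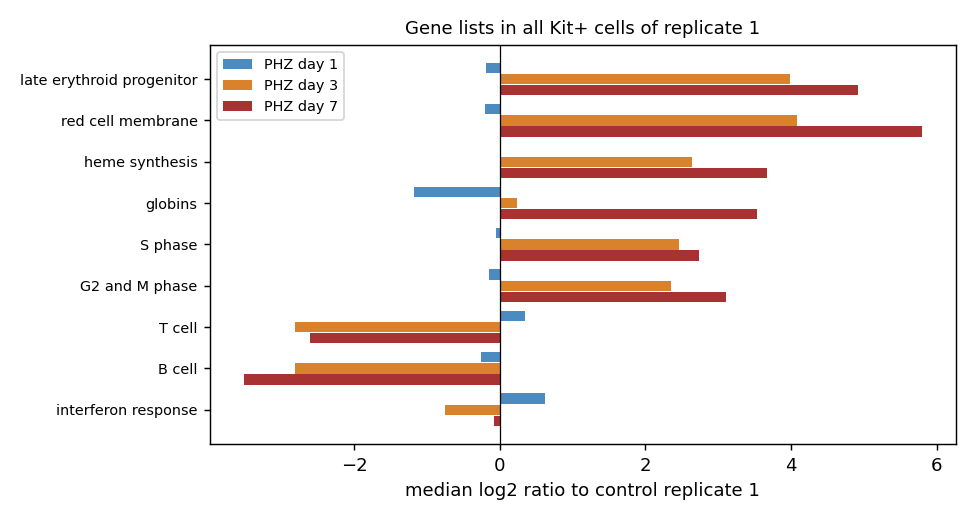
Median log2 ratio to control replicate 1 (horizontal axis) of 9 gene lists in all Kit+ cells of replicate 1 on days 1, 3 and 7. Late erythroid progenitor genes had medians of -0.19, 3.99 and 4.92, and globins -1.18, 0.23 and 3.53.

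Cell cycle shares at equal depth followed the same days. Cells with at least 2 S phase UMIs among 1000 were 44.2% and 49.5% in controls and 82.2% and 97.0% on day 3. The mean was 46.8% ± 3.79 (SD, n = 2) in controls and 89.6% ± 10.4 (SD, n = 2) on day 3. The share was 47.5% (95% interval 45.8% to 49.3%) on day 1 and 94.2% (93.3% to 95.04%) on day 7. For G2 and M phase genes it was 69.4% ± 1.14 (SD, n = 2) in controls and 94.9% ± 4.78 (SD, n = 2) on day 3. Without thinning the S phase means were 65.2% in controls and 97.1% on day 3. Free RNA was not measured or removed, so a cell with 2 UMIs need not be cycling.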

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

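The test of whether control cells of Erythroid5 and Erythroid4 are erythroid was chosen after the result was seen, as were the definition of late erythroid RNA that several tests below use and the medians in own clusters.

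The day 3 effect differed between Erythroid5 and Erythroid4 in 13 genes by the interaction test. Control and day 3 cells of either class lay mostly in different own clusters, so this does not show that erythroid stages responded differently. The differences were 1.89 for Pclaf, 1.96 for Esco2, 2.66 for Brip1, 1.39 for Atad2 and 1.47 for H1f5, and -2.52 for Btg2, -2.01 for Ablim1, -2.76 for Xpo7, -2.80 for Cd36 and -2.46 for Fam117a. Some key genes of replicate 1 had log2 ratios of opposite sign on different days, a difference that was not tested. Gata2 had a log2 ratio of 1.52 on day 3 and -0.45 on day 7. Epor had -0.48 on day 1 and 4.41 on day 7, Klf1 -0.18 and 4.79, Hba-a1 -1.10 and 3.53, and Hbb-bs -0.90 and 3.53. The control 2 to control 1 ratios were 1.58 for Gata2, 0.88 for Epor, 1.19 for Klf1, -2.76 for Hba-a1 and -2.40 for Hbb-bs, larger in size than both Gata2 values and each day 1 value, so opposite movement is not shown. The authors' own phase calls, which no comparison used, put 36.1% and 50.7% of day 3 cells in G2M, above 19.5% and 22.0% in the controls.

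The first pattern is that erythroid genes were higher, and lymphoid and dendritic genes lower, on day 3 within Erythroid5 and Erythroid4. Depth argues least: among cells of at least 1000 UMIs, thinned to 1000, the late erythroid median was still at least 2.73 in both classes, so shallower control cells are excluded as the cause among those, but not among the many left out (class medians were 893 and 991 UMIs). Control cells that are mostly not erythroid would give a low share with late erythroid RNA, and at most 14.5% held it. The markers behind that share include no globin, however, so erythroblasts low in them would count as not erythroid. Globin genes and Alas2 led in Erythroid4 and, with immunoglobulin segments, in the own cluster that held 453 of its 634 control cells. The share therefore does not settle whether the control cells of these classes are erythroid. Whether those cells hold free RNA of a single makeup cannot be told apart from other cells, because the excess of cells with 0 or 1 B cell UMI over a Poisson share was 1.98 and 4.43 points in control replicate 1 but 21.4 and 31.9 points in control replicate 2. A change in erythroid cells themselves may add to it, as heme synthesis genes had a median of 0.78 in cells with late erythroid RNA (0.72 without the 1 member that selects them), a call lost with an estimated correlation (adjusted p = 0.48), and B and T cell genes were lower in the same cells, which leaves a changed background open.

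The second pattern is the rise of S phase and G2 and M phase genes in the whole population. A larger share of erythroid cells alone predicted little S phase rise in other classes, but the median was 1.78 in Monocytes_progenitors and 1.03 in T_Lineage. Of day 3 cells, however, Monocytes_progenitors held only 2.37% and 1.07%, and T_Lineage 1.74% and 0.70%. Medians in such small classes cannot decide where the rise in RNA summed over all cells came from. Erythroid RNA in those cells may be part of both medians. Relative to the rise in late erythroid RNA, the S phase rise in CPM was 5.68-fold and 2.01-fold in Monocytes_progenitors. It was 1.44-fold and 3.11-fold in T_Lineage. In day 3 Erythroid1 the ratio of the levels was 1.24 and 1.16, and the ratio of the rises was 3.555 and 1.927. The lower values of T_Lineage and Monocytes_progenitors therefore exclude little. In B_Lineage the S phase rise was 1.93-fold and 1.20-fold the late erythroid rise. The latter lies near the Erythroid1 levels, so B_Lineage excludes little too. In the own clusters with most cells of Monocytes_progenitors and T_Lineage the S phase medians were 1.14 and 0.50. The prediction therefore failed in both classes, but how much of the whole population's rise lay outside erythroid cells is not decided. Cells of other types grouped in Monocytes_progenitors stay open too. Higher S phase expression within erythroid cells is consistent with a median of 0.63 in cells with late erythroid RNA, a call lost with an estimated correlation (adjusted p = 0.48).

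The third pattern is the fall of T and NK cell genes in the whole population. Dilution by added erythroid cells alone predicts an unchanged share of T_Lineage and NK_cells among cells without late erythroid RNA. That share was 6.37% and 16.8% in controls and 5.35% and 3.78% on day 3. It lay under both controls in both day 3 libraries, but the 95% intervals of control replicate 1 (5.66% to 7.15%) and day 3 replicate 1 (4.22% to 6.68%) meet. Dilution alone and a loss of these cells therefore cannot be told apart, and the spread between the controls keeps it open.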

How the results depend on the processing

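The lineage sums, the split by late erythroid RNA, its use in place of the classes and the total without Erythroid4 and Erythroid5 were tests chosen after the data were seen. The cause of each change below was not tested unless stated.

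All Kit+ cells had 6142 calls, against 3014 with cells thinned to 1000 UMIs, which removes counts (2935 shared), and 3858 to 5530 with 1 library left out. For day 3 against control, within cell classes, the total over 13 classes was 20686, against 13396 by DESeq2, 6586 thinned, 804 over own clusters (6 fitted), 12309 without Erythroid4 and Erythroid5, 2097 in cells with late erythroid RNA, and 9022 to 23399 with 1 library left out. The thinned total covers only classes that still held at least 20 cells in each library, so it need not cover the same classes. Thinned counts were 505 in Erythroid1, 1881 in Erythroid4, 2295 in Erythroid5, 308 in HSPCs, 3 in T_Lineage and 46 in Monocytes_progenitors. Without a filter on low counts, Erythroid1 had 2658 calls, B_Lineage 506, T_Lineage 113, Monocytes_progenitors 889 and the class comparison 180. DESeq2 called 895 in HSPCs, 207 in B_Lineage and 29 in T_Lineage. With cells of at least 1000 UMIs T_Lineage had 8 and the class comparison 23. With 1 library left out the ranges were 485 to 2681 in Erythroid1, 2349 to 3554 in Erythroid4, 2664 to 5028 in Erythroid5, 319 to 2350 in HSPCs, 25 to 2274 in B_Lineage, 30 to 65 in T_Lineage, 17 to 1065 in Monocytes_progenitors, 846 to 1701 in cells with late erythroid RNA and 0 to 507 in the class comparison. Class shares past the test numbered 3 with own clusters, all higher, 3 with lineages, all lower, and 2 with the split by late erythroid RNA, against 0. With an estimated correlation 0 gene lists passed, against 21 by camera at the preset value.

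With a replicate block, B_Lineage had 412 calls, T_Lineage 100, Monocytes_progenitors 448 and cells with late erythroid RNA 3302; the block left the other counts within 1.5 times, all Kit+ cells at 7545. Deviations of same-numbered libraries correlated at 0.27 over 16964 genes, and 2 pairs do not show that numbers pair mice.

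The S phase difference between day 3 and control, 42.8 points, was 55.8 at 500 UMIs and 55.9 with at least 3 UMIs; for G2 and M phase, 25.5 points became 45.4 and 40.2. Signs turned in HSPCs for Bop1 (-0.079, thinned). In the time course with the mean of both controls as reference, day 1 ratios became -0.59 for Gata1, -0.092 for Tfrc, -0.17 for Pcna, -0.0065 for Atp5b, -0.24 for Atf4, 0.14 for Ighm, 0.20 for Igkc, -0.56 for Ccl5 and -0.75 for Nkg7. Day 3 ratios became -0.0023 for Atf4 and 0.17 for Prg2, and day 7 ratios 0.054 for Lyl1 and -0.26 for Atf4. TMM scaling gave 0.040 for Ikzf1 and 0.088 for Ftl1 on day 3, and 0.18 for Kit, 0.16 for Lyl1, 0.23 for Ftl1 and 0.27 for Ldha on day 7; Ldha was 0.035 without globins in the totals. With 1 library left out, log2 fold changes ran from -1.16 to 1.09 for Hba-a1 in Erythroid4. In HSPCs they ran from -3.68 to 0.48 for Ifi27l2a, -4.26 to 0.0062 for Ly6c2, -11.41 to 7.78 for Siglech and -5.83 to 0.13 for Ly6d. In Monocytes_progenitors they ran from -1.57 to 3.63 for Hbb-bs, -1.64 to 5.35 for Lyz2 and -2.34 to 1.08 for Jchain. In T_Lineage they ran from -3.10 to 4.39 for Hbb-bs, -2.55 to 4.55 for Hbb-bt and -2.87 to 3.36 for Igkc.

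Of 6258 gene values with 1 library left out, 4708 kept their side of the threshold, 1334 lost and 205 gained a call. Of 11121 under other alternatives 10364 kept their side, 567 lost and 189 gained a call. Genes called in the main test also had to keep their direction, and others did not. In the class comparison 19 of 40 gene values lost their call with 1 library left out. Of 1344 time course values 421 moved outside their interval and 20 turned sign under other alternatives. A turn was counted only where the whole interval had the same sign. Of 136 gene list results 6 calls were lost and 11 gained with 1 library left out, and of 135 under other alternatives 32 were lost and 5 gained. Leaving out the top 5% of cells, globin genes or using RLE factors left the all-cell count within 1.5 times.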

Other observations

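The list levels, own cluster median and per-cell shares in Monocytes_progenitors and the shares among cells without late erythroid RNA were computed after the data were seen.

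In Monocytes_progenitors, the G2 and M phase list stood at 2207 and 2095 CPM in controls and at 7302 and 8783 CPM on day 3, while the late erythroid list went from 386 and 407 CPM to 843 and 2218 CPM. The rise of the former was 11.5-fold and 3.64-fold that of the latter, and in day 3 Erythroid1 the level of the former was 1.47-fold and 1.26-fold that of the latter. In Erythroid1 the rise of the former was 2.884-fold and 1.105-fold that of the latter. Cells with at least 10 G2 and M phase UMIs among 1000 were 0 of 208 and 1 of 239 in controls and 12 of 82 and 16 of 71 on day 3. At the lower threshold of 2 UMIs, the one fixed for the cell cycle comparison, the shares were 59.1% (95% interval 52.1% to 65.9%) and 59.4% (52.9% to 65.7%) in controls and 72.0% (60.9% to 81.3%) and 78.9% (67.6% to 87.7%) on day 3, and the intervals of replicate 1 meet. The median cell held 2 such UMIs in both controls and day 3 replicate 1, and 4 in day 3 replicate 2. The list median was 3.51, ran from 2.58 with cells thinned to 1000 UMIs to 3.71 without control replicate 2, and was 0.93 in the own cluster with most of these cells. Markers of other cells differed in the class too: the neutrophil gene S100a8 had 14.4 and 5.84 CPM in controls and 694 and 28.5 CPM on day 3, and Lyz2 868 and 70.1 CPM and 5825 and 159 CPM.

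Among cells without late erythroid RNA, the classes that the authors named for neutrophils took 2.15% and 3.89% in controls and 13.8% and 4.30% on day 3. The interval of day 3 replicate 2 (3.34% to 5.44%) holds the value of control replicate 2. Macrophages_progenitors took 3.40% and 3.83% in controls and 3.08% and 0.587% on day 3. In B_Lineage, the rise of the G2 and M phase list was 2.58-fold and 1.37-fold that of the late erythroid list.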
